A study of Mus musculus with 10 samples.

How the data were processed

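HEB, the protein of the gene Tcf12, is a helix-loop-helix transcription factor of the E-protein class, and ID4 is a helix-loop-helix protein without a DNA-binding domain that pairs with such factors. Chromatin immunoprecipitation with an antibody against HEB followed by sequencing was carried out in Comma-Dβ cells, a mouse mammary epithelial line, at passage 28. Per the labels, cells received 20 nM of an siRNA pool against Id4 (siID4) or of a non-targeting pool (siNT) and were harvested 48 h after transfection. The labels list 10 libraries: 3 HEB libraries with siNT, 3 with siID4 and 4 input libraries without immunoprecipitation that serve both arms.

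The authors deposited 2 lists of peak summits, 1 per siRNA, and no values per library are used here. Each row gives a position of 1 bp, a peak name and a score. The score is read from the layout as a −log10 q value given by the authors' peak caller, which the sources used here do not state; its minimum was 1.32 in the siNT list and 1.31 in the siID4 list, just above 1.30, which is −log10 of 0.05. The genome build was mm10 and SAMtools was used, per the submitters' processing notes. The aligner, the peak caller and the removal of any regions are not given in the sources used here. Nor is it given whether or how the 3 libraries of each siRNA were combined. Peak names are numbered up to 598 in the siNT list and 1540 in the siID4 list, and 38 and 51 of these numbers are absent from the rows. The read depth of each library is unknown, so no value below carries an error between replicates. Intervals are exact binomial (Clopper-Pearson) 95% intervals over summits and cover counting error only. Tests over summits describe these 2 lists, because summits are not replicates of a treatment. Both lists rest on the same inputs, so their noise is not independent. A score depends on the depth of its own list and is used to rank or filter summits within a list. The same score limit of 5 or 10 need not be equally strict in both lists, so ratios of summits above it depend on the unknown depths.

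Positions are 1-based mm10 coordinates. Genes came from a RefSeq table of GRCm38, the assembly behind mm10, with 21 chromosomes; it pairs each symbol with a start and an end but no strand, exon or transcription start site. The planned link to the nearest transcription start site was therefore replaced by the nearest protein-coding gene body within 100000 bp, with ties inside overlapping genes broken by the nearer gene end. The planned classes of promoter, exon and intron were replaced by 3 classes over all annotated genes: within 1000 bp of either end of a gene, otherwise inside a gene, and outside genes. No genome sequence was used, so the planned tests of E-boxes (the CANNTG sites of helix-loop-helix factors), other motifs and 6-base words were not run.

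A summit was called shared when the other list held a summit within 200 bp. Sharing was set beside 100 random placements of each summit on its own chromosome, and beside 100 random shifts of up to 500 kb. Expected shares for locations, gene lists and chromosomes were computed from positions every 500 bp over the span that genes or summits reach on each chromosome. Locations and chromosomes were tested with two-sided exact binomial tests, gene lists with one-sided exact binomial tests, and differences between the lists with two-sided Fisher's exact tests, each adjusted by Benjamini-Hochberg within its family. Ranks were compared with a permutation test of 100000 resamples. Summits on unplaced scaffolds have no gene annotation and entered counts and sharing only. The 17 gene lists, the rule for named genes and the tests, apart from the replacements above, were fixed before the data were examined. Sharing by quartile of the score, chromosome shares between the lists, the distal chromosome 11 region, repeated sequence, gene ends by sharing and histone genes were examined only after the data were seen, and the border of that region and the score limit of 10 were set from the data. Every gene of the lists matched a protein-coding symbol. The rule took the genes linked to the 15 highest-scoring siID4 and the 10 highest-scoring siNT summits, the genes at the 10 highest siID4 and 5 highest siNT summits with no summit of the other list within 1000 bp, the 5 genes with the most siID4 summits, up to 4 members per gene list, and Id4 and Tcf12. After the data were seen, the highest-scoring summits of this rule were read as those that could be linked within 100000 bp, because many of the highest lay on scaffolds or far from genes, and members of gene lists were taken separately in each list of summits.

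Results were also computed with other sharing distances, a score above the list's median or of at least 5, merging of summits within 500 bp, other link and gene-end distances, protein-coding genes only, genes counted once, and autosomes and X only. Further settings, chosen after seeing the data, left out chromosome 11 beyond 110 Mb or repeated sequence, took expected shares within 2 Mb of each summit, or used the nearer gene end. Repeated sequence here means only the unplaced scaffolds and the first 3.1 Mb of chromosome 9. The functions were tested on simulated data: nearest gene and location differed from a direct search at 0 of 300 positions. In 20 pairs of randomly placed lists of the same sizes, a gene list was called in 0 pairs and a location class in 1. These lists were placed evenly, as the tests assume, so they do not show how often crowded lists give calls. A planted sharing of 49.9% was recovered as 50.1%. Calculations used Python 3.11, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.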

Results

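HEB binding sites were mapped in Comma-Dβ mouse mammary epithelial cells after knockdown of Id4 and after a non-targeting siRNA. The labels list 3 libraries per siRNA, and the authors deposited 1 list of peak summits for each siRNA. The siID4 list held 1489 summits and the siNT list 560. Of these, 1394 and 483 lay on assembled chromosomes and 95 and 77 on unplaced scaffolds. The median score was 4.31 in the siID4 list, with an interquartile range of 2.60 to 7.72, and 6.68 in the siNT list, with a range of 3.26 to 13.8. The depth of the libraries is unknown, the number of summits has no replicate check, and scores are not comparable between the lists. The lists hold no expression values, so the knockdown of Id4 itself was not measured here.

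The first comparison asked how HEB occupancy differed when Id4 was knocked down. The siID4 list held 2.66 times as many summits as the siNT list (95% interval 2.41 to 2.94, counting error only). The ratio was 1.85 (1.61 to 2.11) among summits with a score of at least 5 and 1.37 (1.14 to 1.65; 284 against 207 summits) at a score of at least 10, a limit chosen after the data were seen. Equal score limits need not be equally strict in lists of unknown depth. Of the summits on chromosomes, 1171 in the siID4 list lay within 100000 bp of 761 protein-coding genes and 427 in the siNT list of 336 genes, and 228 genes were linked in both. The lists had 290 summits in common, which were 51.8% of the siNT list (47.6 to 56.0) and 19.5% of the siID4 list (17.5 to 21.6). The siNT list is 37.6% as long as the siID4 list, which limits the siID4 share; with equally many highest-scoring siID4 summits the share was 44.1% of either list. Shared summits lay a median of 13 bp apart. On assembled chromosomes, where 47.4% of siNT summits were shared, random placement on the same chromosome gave a mean of 0.0435% and at most 0.414%, and random shifts of up to 500 kb gave at most 1.04%.

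Sharing increased with the score in both lists. In the siNT list, 15% of the lowest quartile of scores and 90% of the highest quartile had an siID4 summit within 200 bp. In the siID4 list the shares were 2.41% and 57.8%. Shared siID4 summits stood at a median percentile of 87.8 of their list and siID4-only summits at 41.9, a difference of 45.9 percentile points (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). The same contrast in the siNT list was 70.4 against 28.04 (permutation test, p = 1e-05).

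**Figure D1:**
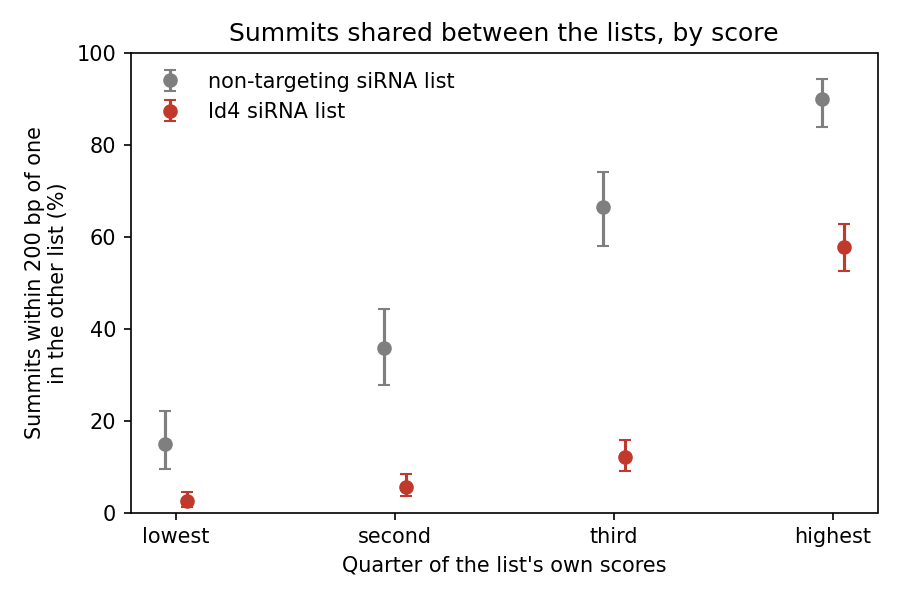
Share of summits with a summit of the other list within 200 bp (y axis, percent) by quartile of the list's own scores (x axis), for the non-targeting list (grey) and the Id4 siRNA list (red); bars are exact 95% binomial intervals. In the non-targeting list the share goes from 15% in the lowest to 90% in the highest quartile, and in the Id4 siRNA list from 2.41% to 57.8%.

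The very highest scores lay on unplaced scaffolds, which have no gene annotation, and at the start of chromosome 9, over 100000 bp from any protein-coding gene. Among the sites that could be linked to a gene, the highest score in both lists lay inside H3f3b, which encodes the replication-independent histone H3.3, at position 116024732 of chromosome 11 in the siID4 list (score 286) and 27 bp away in the siNT list (score 190). The next was 81 bp from H1f2, a linker histone gene, at position 23738726 of chromosome 13 (score 178), with an siNT summit 2 bp away (score 157). The linker histone genes H1f4 and H1f3 also carried siID4 summits among the 15 highest, 103 bp and 109 bp from a gene end with scores of 84.8 and 62.8. Both had an siNT summit within 200 bp.

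Of the 15 highest linked siID4 summits, 14 had an siNT summit within 200 bp; the exception was the site near Gtpbp4. A summit 45460 bp from Cd200, a cell-surface glycoprotein gene, scored 88.8. A summit inside Cbfa2t3, a transcriptional corepressor of the ETO family, at position 122661264 of chromosome 8 scored 82.2. Sites 3327 bp from Tmem125 and 15136 bp from Gm40035 fell on the same base in both lists, with siID4 scores of 75.6 and 68.8. Summits lay inside Sema5a, a semaphorin gene (score 67.9), and Afap1l2, an actin filament-associated adaptor gene (score 67.4). A summit 124 bp from Lrpprc, which acts in mitochondrial RNA metabolism, scored 64.6. A summit inside Pcolce, whose product enhances procollagen processing, lay 121 bp from a gene end at position 137611401 of chromosome 5 (score 55.6). The remaining sites lay 18844 bp from 1600014C23Rik (score 61.9) and 81957 bp from Vmn1r2, a vomeronasal receptor gene (score 51.0). The latter summit lay near the start of chromosome 4, at position 3090126, and mappability was not analysed here. The 10 highest siNT sites added Nav1 (score 75.9) and Arid3a, a DNA-binding protein gene (score 49.3), each with an siID4 summit within 200 bp.

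The siID4-only and siNT-only sites named here had no summit of the other list within 1000 bp. The highest siID4-only summit linked to a gene lay 15679 bp from Gtpbp4, a ribosome biogenesis gene, at position 9011795 of chromosome 13 (score 62.1, rank 29 of 1489). It was followed by summits 839 bp from Duxf3 (score 34.4), inside Mdga2 (27.1), 10165 bp from Nfatc2, a transcription factor gene of calcium signalling (22.1), and 1484 bp from Evpl, the gene of the epithelial protein envoplakin (20.8). Summits near or inside Gm21119, Ift140, Hopx, Sfi1 and Syne3 scored between 16.9 and 20.5. The Sfi1 summit lay near the start of chromosome 11, at position 3161588, and Sfi1 was linked to 7 siID4 and 6 siNT summits. Duxf3 belongs to a family of near-identical copies, so its position may be uncertain, but mappability was not analysed here. The highest linked siNT-only summits lay inside Gm11567 (score 31.3), 18123 bp from Gm21119 (24.8) and inside it (17.1), 16037 bp from Gm15319 (17.2) and inside Bahcc1 (15.6). The siNT-only summit 18123 bp from Gm21119 lay 1273 bp from the siID4-only summit near that gene, just beyond the 1000 bp limit. The siID4-only summit near Duxf3 had an siNT summit 1412 bp away. These sites are therefore not read as specific to either siRNA. The Gm21119 and Gm15319 summits lay between 20 and 21 Mb of chromosome 8, which held 26 siID4 and 18 siNT summits. H3f3b, Evpl and Bahcc1 lie in the crowded part of chromosome 11 described further on.

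Id4 had no summit within 100000 bp in either list; the nearest lay 3.05 Mb away in both. Tcf12, the gene of HEB, contained a summit in the siID4 list at position 71888592 of chromosome 9 (score 6.60, rank 452), and the nearest siNT summit was 14.4 Mb away.

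A second question was whether sites lay near genes of mammary lineages and of the pathways around HEB and ID4. The share of summits linked to a list did not differ between siID4 and siNT for any of the 17 lists (two-sided Fisher's exact test, 0 lists at an adjusted p under 0.05; the smallest unadjusted p was 0.274). Of 29 helix-loop-helix and ID genes, 3 had an siID4 summit and 2 an siNT summit. Id3, an ID family gene, had a shared summit 3242 bp away at position 136140580 of chromosome 4 (siID4 score 35.4), and Atoh8, a helix-loop-helix factor gene, one inside it (35.4). With 4 siID4 summits against 1.65 expected, this list did not pass the exact binomial test (adjusted p = 0.353). Of the other settings it passed only at a score of at least 5. It did not pass above the median score, with each gene counted once or with expected shares within 2 Mb.

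Of 47 extracellular matrix genes, 5 were linked in the siID4 list (Col18a1, Col1a2, Col3a1, Fbln2 and, named only after its values were seen, Col4a2) and 3 in the siNT list (Col16a1, Col1a1 and Col3a1). The site near Col3a1, a fibrillar collagen gene, was shared, 23392 bp from the gene with an siID4 score of 23.5, and the summit inside Col18a1 scored 13.1. The 5 summits compared with 3.25 expected (exact binomial test, adjusted p = 0.485). Of 24 contractile and smooth muscle genes, Actg2, a smooth muscle actin gene, contained 1 siID4 summit (score 2.72, rank 1097), against 1.20 expected, and none was linked in the siNT list. Of 22 basal epithelial genes only Sox9 was linked, with 5 siID4 summits; these lie in the crowded part of chromosome 11 (5 against 2.62 expected; exact binomial test, adjusted p = 0.353). Of 28 luminal genes, Krt8, a luminal keratin gene, had an siID4 summit 1175 bp away (score 12.2), and Epcam an siNT summit 64754 bp away (score 5.78).

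Of 28 Wnt pathway genes, Tcf7l1, a Wnt-responsive transcription factor gene, contained a shared summit (siID4 score 32.3) and Wnt10a, a Wnt ligand gene, had one 4093 bp away (13.1); Fzd1 was linked in the siID4 list only (1.90). With 4 siID4 and 3 siNT summits against 1.83 and 0.634 expected, the list did not pass in either (exact binomial test, adjusted p = 0.353 and 0.225). In the Notch list Maml3, a Notch coactivator gene, had a shared site. In the TGF-beta and BMP list, Tgfbr3 had a shared site and Nog an siID4 site. Among adhesion, actin and YAP genes, Wwtr1 contained a shared site, Pxn an siID4 site, and Rnd3 an siNT site. Myc and Dusp1 were the AP-1 and early-response genes linked in the siID4 list. Of the markers of other cell types, fibroblast genes (Col14a1 and Pdgfra) had 3 siID4 summits and endothelial genes (Cdh5, Kdr and Vwf) 3, neither past the exact binomial test (adjusted p = 0.153 for both). The Cdh5 site was shared, and it was the only endothelial or fibroblast site in the siNT list. None of the 15 immune markers, 15 regulators of the epithelial-mesenchymal transition and 23 ribosomal protein genes of these lists was linked in either list of summits, and of the 26 cell cycle genes only Mcm3 was, in the siID4 list.

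The neuronal comparison list was the only list above random placement, in both lists, and a single gene carried it. Rbfox3, which encodes the neuronal splicing factor NeuN and lies on chromosome 11 from 118489760 to 118911597, was linked to 40 siID4 and 10 siNT summits against 7.18 and 2.49 expected for the whole list (exact binomial test, adjusted p = 2.3e-16 and 0.0043). With each gene counted once, or without chromosome 11 beyond 110 Mb, 0 lists passed in either list of summits. With expected shares within 2 Mb the call held in siID4 (40 against 19.6 expected; adjusted p = 0.000139, exact test) and was lost in siNT (10 against 4.09 expected; adjusted p = 0.0881, exact test), where it was also lost above the median score and at a score of at least 5.

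Rbfox3 was part of a wider concentration on distal chromosome 11. The 5 genes with the most siID4 summits were Rbfox3 (40 siID4 and 10 siNT summits), Ccdc57 (16 and 1), Bahcc1 (14 and 3), Sdk2 (10 and 6) and Gm40469 (9 and 5). The first 4 lie on chromosome 11 beyond 110 Mb. From 110000001 to 121925328 the siID4 list held 333 summits, 22.4% of all its summits, and the siNT list 57, or 10.2%. On assembled chromosomes these were 54.1 times (49.1 to 59.4) and 26.7 times (20.5 to 34.0) the number expected by length. The share was higher in the siID4 list (Fisher's exact test, odds ratio 2.54, p = 5.85e-11), with a ratio of summits of 5.84 (4.40 to 7.88) in the region and 2.30 (2.07 to 2.56) elsewhere. Within their lists these summits scored low, with a median percentile of 38.4 in siID4 and 22.8 in siNT, and 11 summits of each list there were shared, 3.30% of the 333 siID4 and 19.3% of the 57 siNT summits.

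**Figure D2:**
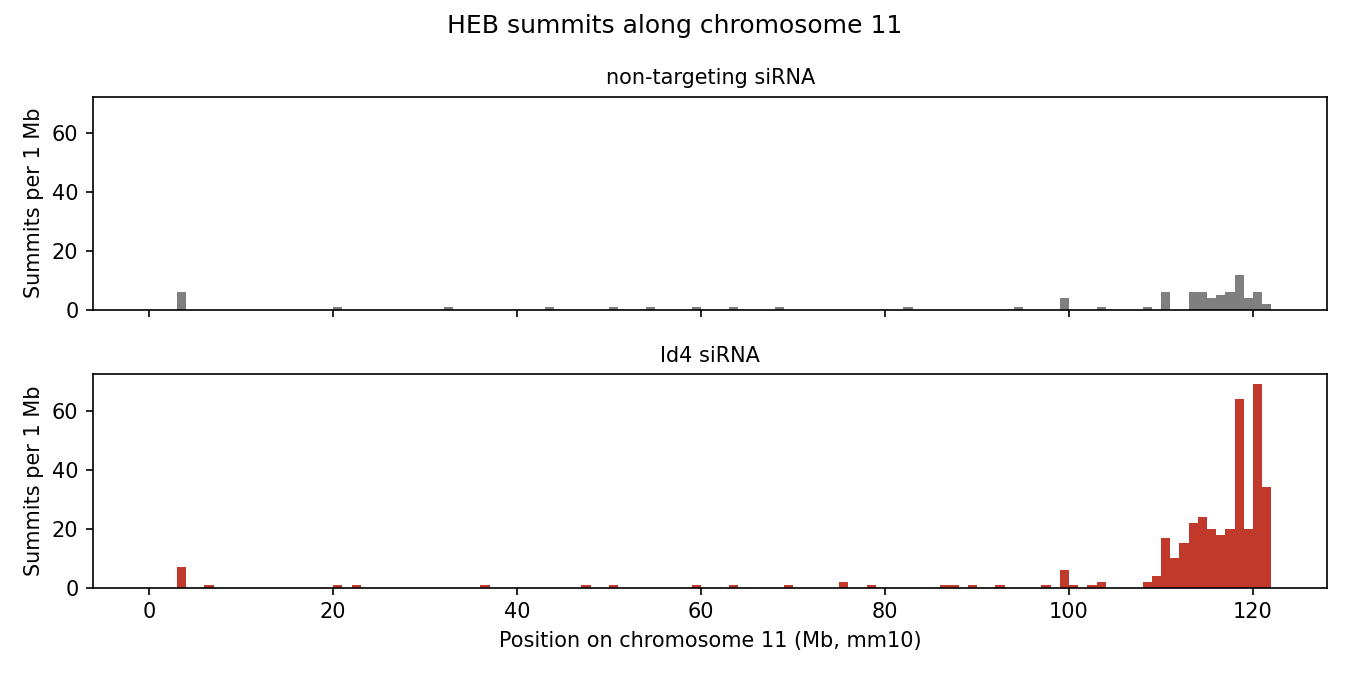
Number of HEB summits per 1 Mb (y axis) along chromosome 11 in mm10 (x axis, Mb) for the non-targeting list (top) and the Id4 siRNA list (bottom), on the same scale. Summits crowd beyond 110 Mb in both lists, with up to 12 per bin in the non-targeting list and up to 69 in the Id4 siRNA list.

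Chromosome 11 as a whole held 5.93 times the expected number of siID4 summits and 3.63 times that of siNT summits. At a score of at least 5 these were 3.88 and 2.37 times, and above the median score 4.75 and 1.86 times (adjusted p = 0.0461 for the last, exact binomial test). Other chromosomes also departed from their length. Copy number, input coverage and mappability were not analysed, so departures from length are not read as HEB preferences for whole chromosomes. Chromosome 5 held 2.67 times the expected number of siID4 summits and 2.55 times that of siNT summits, and chromosome 15 held 2.52 and 2.15 times (exact binomial tests, adjusted p of 5.42e-05 or lower for each). With chromosome 11 these were the 3 chromosomes above expectation in the siNT list. The siID4 list had a 4th, chromosome 1, at 1.36 times (adjusted p = 0.000453, exact binomial test) against 1.003 in siNT; the share on chromosome 1 did not pass between the lists (Fisher's exact test, adjusted p = 0.291). Chromosomes 2, 3, 10, 12, 13, 14 and 18 were below expectation in both lists, with 3 siID4 and 2 siNT summits on chromosome 18. Y was below expectation too, but whether these cells carry it was not examined, so its count says nothing about binding. Between the lists, the share on chromosome 11 was higher in siID4 (26.8% against 16.4%; Fisher's exact test, adjusted p = 5.31e-05) and that on X lower (1.72% against 4.35%; Fisher's exact test, adjusted p = 0.0287). Without chromosome 11 beyond 110 Mb, 0 chromosomes differed in Fisher's exact test (smallest adjusted p = 0.124, for chromosome 1 and X; unadjusted p = 0.0118 and 0.011). The comparisons of chromosome shares between the lists and of the distal region were chosen after the data were seen.

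**Figure D3:**
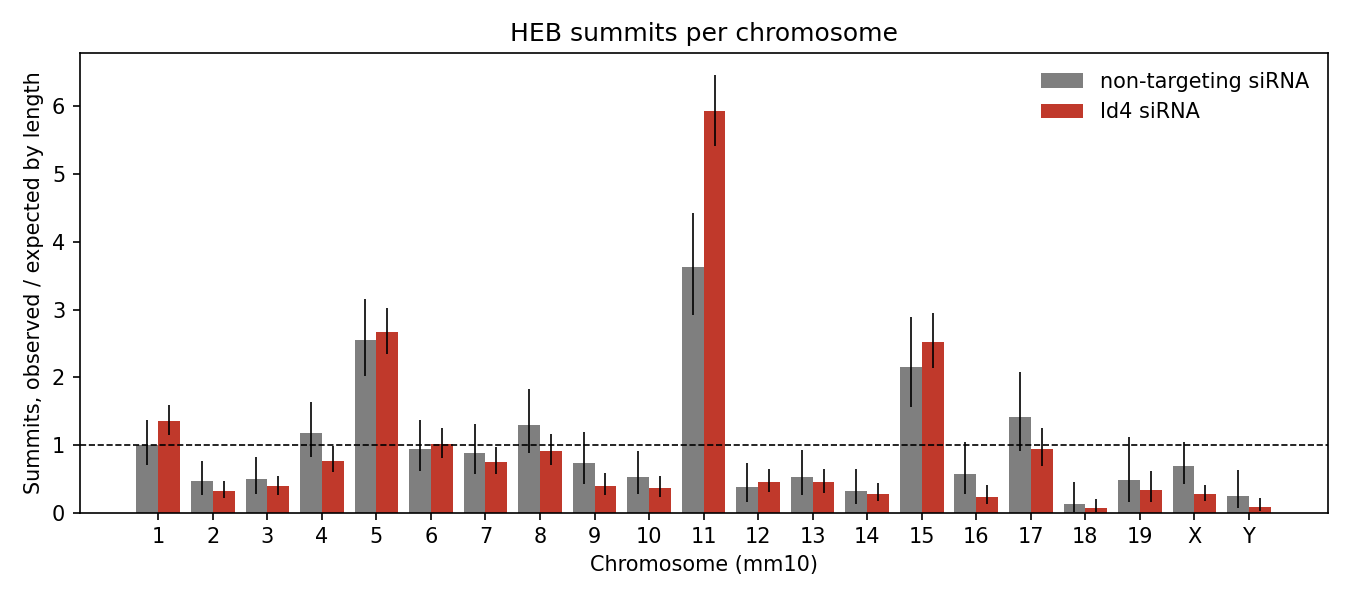
Observed over expected number of HEB summits by chromosome length (y axis) for each chromosome (x axis) in the non-targeting list (grey) and the Id4 siRNA list (red); bars start at 0, whiskers are exact 95% binomial intervals and the dashed line marks the expected number. Chromosome 11 reaches 3.63 and 5.93, and chromosomes 5 and 15 exceed 2 in both lists.

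Summits lay near gene ends more often than random positions. In the siNT list 12.0% of summits (9.25 to 15.2) and in the siID4 list 9.47% (7.98 to 11.1) lay within 1000 bp of a start or end of an annotated gene, against 6.05% of positions (exact binomial tests, adjusted p = 2.41e-06 and 9.93e-07). A further 42.4% and 47.5% lay inside genes, 1.0004 and 1.12 times the expected share (exact binomial tests, adjusted p = 1 and 0.000147). Outside genes lay 45.5% and 43.0%, or 0.884 and 0.835 times (exact binomial tests, adjusted p = 0.0141 and 7.02e-10). Against positions within 2 Mb of each summit, which allows for gene-rich regions, the siNT ratio was 1.397 (adjusted p = 0.0323, exact Poisson-binomial test) and the siID4 ratio 1.10 (adjusted p = 0.263, same exact test), so the siID4 call was lost. The 3 calls inside and outside genes were lost too, and a lower siNT share inside genes passed (0.893 times, adjusted p = 0.0323, same exact test). Without chromosome 11 beyond 110 Mb, the siID4 excess inside genes was also lost (1.05 times, adjusted p = 0.203, exact binomial test). So it was with gene ends within 3000 bp (1.06 times, adjusted p = 0.0674, exact binomial test). The siNT deficit outside genes was lost without that region (0.920 times), with protein-coding genes only (0.986) and above the median score (0.864). For protein-coding gene ends, 7.86% of shared and 3.43% of siID4-only summits lay within 1000 bp (Fisher's exact test, p = 0.00554), a contrast chosen after the data were seen. In the siNT list the shares were 7.42% of shared and 5.12% of siNT-only summits, which did not pass (Fisher's exact test, p = 0.347). Shared summits also scored higher in both lists, and no contrast at matched scores was made. Sharing and score therefore cannot be told apart here.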

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

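The tests of chromosome 11 in the siNT list, both tests of repeated sequence, including their form at a score of 10 or more, the shares at a score of 10 or more and in the highest quartile, and the ratio without chromosome 11 beyond 110 Mb were chosen after the results were seen.

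Unplaced scaffolds, which have no gene annotation and enter no gene comparison, held 95 siID4 and 77 siNT summits, above the limit that a count of 0 allows. With the first 3.1 Mb of chromosome 9 they gave 8 of the 10 highest siID4 scores and 9 of the 10 highest siNT scores, up to 2053 and 1988. Repeated sequence that piles up reads whatever the siRNA is a candidate explanation: 65.3% of the siID4 summits there were shared against 16.1% elsewhere (two-sided Fisher's exact test, odds ratio 9.80, p = 7.73e-26), but sharing rises with the score, and at a score of 10 or more the contrast narrowed to 76.9% against 63.01% (odds ratio 1.96, p = 0.038, Fisher's exact test). Whether binding was gained there with the Id4 siRNA cannot be told apart: the ratio of siID4 to siNT summits was 1.23 (0.911 to 1.67) there and 2.90 elsewhere, while at a score of 10 or more it was 1.3 (0.885 to 1.92) and 1.39. Neither input coverage, mappability nor a repeat annotation was analysed here, so these places are called repeated from their position alone.

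The crowding of summits on chromosome 11 beyond 110 Mb may reflect a gained region with raised coverage in these cells. The siNT list was crowded there too, at 26.7 times the expected number (20.5 to 34.0), but this was seen together with the pattern and is no test of it; no coverage was analysed here, so a gain and other sources of crowding cannot be told apart. The ratio of siID4 to siNT summits was higher there (5.84) than elsewhere (2.30). A gain common to both arms was not tested as a source of this difference, as the depths are unknown. Whether more near-threshold calls in the siID4 list account for that cannot be told apart either: at a score of 10 or more the region held only 8 and 5 summits, a ratio of 1.60 (0.462 to 6.22), an interval that holds both the ratio elsewhere (1.37) and the full one, and this limit need not be equally strict in both lists. A regional effect of the knockdown stays open.

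Crowding on chromosome 11 alone is argued against as the source of the larger siID4 list, since the ratio without the region was 2.30 (2.07 to 2.56). Deeper or cleaner siID4 libraries over one set of sites would recover nearly all stronger siNT sites, set by hand at 90% before the result was seen. Of the siNT summits above their list's median score, the set fixed beforehand, 78.1% (72.8 to 82.8) were shared. The interval lay below 90%, so the prediction failed as it was written. The share rises with the score, to 84.1% (78.3 to 88.8) at a score of 10 or more and 90% (83.8 to 94.4) in the highest quartile. Both of these limits were chosen after the results were seen, and only the highest quartile reached 90%. The 90% was assumed and is no firm bound, so the explanation was left undecided, a choice made after this result. Deeper or cleaner siID4 libraries and a gain of HEB sites after Id4 knockdown therefore cannot be told apart here. Only 1 list of unknown depth is at hand for each siRNA.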

How the results depend on the processing

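The settings that left out chromosome 11 beyond 110 Mb or repeated sequence, that took expected shares within 2 Mb, or that used the nearer gene end or a score of at least 10 were chosen after the data were seen. No paired analysis was possible because the deposited lists hold no values per library; for the same reason no replicate could be left out. The planned motif and 6-base word tests were not run, as no genome sequence was used. The ratio of list sizes fell to 1.85 at a score of at least 5, to 1.37 at a score of at least 10 and to 2.30 without chromosome 11 beyond 110 Mb, and stayed above 1 in these and when summits were merged or sequences left out; above the median score it is fixed by construction. The shared percent of the siNT and siID4 lists was 43.6 and 16.4 at 50 bp, 56.6 and 21.4 at 500 bp, 59.3 and 23.0 at 1000 bp, 77.1 and 28.9 above the median score, 69.4 and 37.6 at a score of at least 5, 44.1 and 44.1 with equally many highest siID4 summits, and 55.5 and 24.1 without chromosome 11 beyond 110 Mb. The higher rank of shared siID4 summits held under its 4 alternatives. With expected shares within 2 Mb, the siID4 gene-end ratio was 1.10 and no longer passed. Inside genes the siNT ratio of 1.0004, which had no direction, became 0.893 and passed (adjusted p = 0.0323, exact test), and the siID4 ratio went from 1.12 to 0.952. Outside genes 0.884 and 0.835 became 1.04 in both, so the 3 calls inside and outside genes were lost. In this setting the expected share near gene ends was 8.59% for siNT and 8.60% for siID4, against 6.05% over whole chromosomes. The siID4 call inside genes was also lost without chromosome 11 beyond 110 Mb and with gene ends within 3000 bp. The siNT call outside genes was also lost without that region, with protein-coding genes only and above the median score. The 1 gene list called in each list became 0 in both with each gene counted once and without chromosome 11 beyond 110 Mb; for siNT it also became 0 above the median score, at a score of at least 5 and with expected shares within 2 Mb. For siID4 it became 2 at a score of at least 5, where the helix-loop-helix list joined, and 3 with links within 1000000 bp, where the basal and fibroblast lists joined; the causes were not tested. Of 107 values recomputed over 17 results, 73 kept their direction and side of the threshold or stayed within the interval. Unknown depth limits every comparison of scores between the lists.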

Other observations

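The contrasts in this part were chosen after the data were seen. Histone genes were counted because H3f3b and H1f2 had been seen among the highest scores, so the count describes the lists and is no test of histone genes as a group. In each list 5 summits lay within 1000 bp of a histone gene, at H1f2, H1f3, H1f4, H1f5 and H3f3b, and these sites were shared within 200 bp. No other of the 102 histone genes searched had a summit at that distance.

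Outside chromosome 11, the most crowded 1 Mb bins were the same places in both lists. The 1 Mb from 20 Mb on chromosome 8, around Gm21119, Gm15319 and Gm40469, held 26 siID4 and 18 siNT summits. The 1 Mb from 15 Mb on chromosome 5, around Gm17019, held 18 and 13, and that from 85 Mb on chromosome 1, around C130026I21Rik, held 29 and 10.

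A last contrast left out chromosome 11 beyond 110 Mb, the unplaced scaffolds and the first 3.1 Mb of chromosome 9. Other crowded places, such as the bins above, stayed in, so repeats were not removed as a class. Here 7.98% of the 213 shared siID4 summits lay within 1000 bp of a protein-coding gene end, against 4.64% of positions within 2 Mb. Of the 842 siID4-only summits 2.26% did, against 3.71% locally, and shared and siID4-only summits differed (Fisher's exact test, p = 0.000186). The siNT list gave 7.98% of shared against 4.33% of siNT-only summits, which did not pass (Fisher's exact test, p = 0.156). These contrasts were not matched for score, and shared summits scored higher, so sharing and score cannot be told apart.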
